A study of Candida albicans with 6 samples.

How the data were processed

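RNA was measured in 6 cultures of Candida albicans SC5314, 3 untreated controls and 3 treated with surfactin at 128 mg/L for 1 h. Per the labels' protocols, pre-cultures grew for 18 h at 37 °C, were diluted to an optical density of 0.1 in 20 mL, and received surfactin after 4 h. Poly-A RNA was captured, libraries were made by random priming, and single 75 bp reads were generated, per the labels' protocols. Samples were grouped by their treatment labels. The design text speaks of cultures in 3 replicates, but nothing says that pre-cultures were separate. The p-values therefore measure only the spread between these samples, which may be technical. Those of limma also draw on the spread of other genes.

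Per the submitters' processing notes, FastQC, STAR and DESeq were used, with no versions. The settings of each tool, the genome build, the counting and the use of strand are not given in the sources used here. The deposited table of 6245 genes holds, per the file headers, normalized log2 values for each library, p-values from the authors' moderated test, their adjusted p-values, a fold change and a log2 fold change. The deposited log2 values are centred by gene, since the median of the 6 libraries is 0 for 100% of the tested genes. They hold no levels and no counts, so the depth of each library is unknown and no counting interval was given. The authors' deposited log2 fold change equals the difference of group means to within 3e-07. The deposited p-values differ by at most 0.00296 on the log10 scale from those of limma without a trend over all 6245 genes.

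Genes listed at 0 in every library, 232 in all, were left out. They comprise 126 tRNA, 75 snoRNA, 5 snRNA, 4 rRNA, 3 ncRNA and 2 other RNA genes and 17 protein-coding genes, and the 6013 genes left are all protein-coding. All 6245 gene identifiers matched the RefSeq table of assembly ASM18296v3, which was used for symbols (2821 of the tested genes), chromosomes and lengths. Since the authors' build is not given, no coordinates are printed. Of those lengths, 95.73% are multiples of 3. Coding lengths would all be, so some may include more than coding sequence, and they are called gene lengths here. In 15 genes the lowest value is shared by 2 or more libraries, which can be a floor. Genes with near-identical copies or overlapping neighbours are uncertain where counting could split their reads.

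The deposited log2 values were tested with limma 3.58.1 in R 4.3.3, with group as the only term, a mean trend in the prior variance, no robust option and Benjamini-Hochberg adjustment at 0.05. The trend follows the mean of centred values, which is not an expression level, and a fit without the trend is among the alternatives. The trend can raise the SE and adjusted p of single genes, as for PGA50 below. The median SE of a log2 difference was 0.0812. Large changes were counted at 2-fold. The 38 gene lists were tested with camera (limma, inter-gene correlation preset to 0.01, Benjamini-Hochberg over the 38 lists). Members were also counted after adjustment over the list alone. Libraries were compared by principal components, by the SD of their differences and by the correlation of deviations from group means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

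Designs, lists, the naming rule and most alternatives were set before the data were examined. The rule names the 12 largest rises and 12 largest falls among genes with a symbol that passed and whose groups do not overlap; for each list described, up to 4 passing members with the largest change and members that moved the other way; and 20 genes whatever their result, such as GSC1, ERG11 and HSP90. A condition on mean level could not be applied to centred values. Of the list members that the rule names, only part are printed below. Alternatives were a replicate block, each library left out in turn, centring of libraries, quantile normalization, genes listed at 0 kept, limma without trend or with the robust option, the authors' deposited p-values, other thresholds (1.5-fold, 3-fold, adjusted p under 0.01), an estimated inter-gene correlation, fry and camera on ranks. Removal of a loess trend on gene length (span 0.5) was added after seeing the data.

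The fit was tested on simulated data over 6013 genes, 200 of them changed, for the comparison of surfactin with control. It recovered 48 of 67 genes (71.64%) with a log2 change of 0.5, 57 of 67 (85.07%) with 1 and 65 of 66 (98.48%) with 2. It called 180 genes in all, 10 of them unchanged, and 0 with the wrong sign, and 0 lists beyond the shifted one. Simulated genes were drawn independently of each other, so the count of lists does not test camera on correlated genes. Far fewer genes were changed in the simulation than passed in the real data.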

Results

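The data describe gene expression in Candida albicans SC5314, a laboratory reference strain of this yeast, in liquid culture with and without surfactin. Surfactin is a cyclic lipopeptide surfactant made by Bacillus subtilis, and the study's title concerns its antifungal effect. The 3 control cultures received none, and the 3 treated cultures received 128 mg/L, with cells collected after 1 h of exposure. Poly-A RNA was sequenced with 75 bp reads, and 6013 protein-coding genes had values other than 0. Values are the authors' normalized log2 expression, with each gene set to 0 at its median over the 6 libraries, so differences between libraries can be read but levels cannot. The number of reads behind each value is unknown. Below, changes are surfactin minus control on the log2 scale, and "passed" refers to limma with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Unless SD is named, ± is limma's moderated SE of that difference with n = 3 per group, which draws on the spread of other genes. For the gap between the ribosome lists, ± is a plain SE over libraries.

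The first comparison asked how far the libraries differ within and between groups. Treated and control libraries lay apart on the first principal component, which held 80.9% of the variance, with scores from 22.03 to 25.69 in the surfactin libraries and from -28.35 to -19.69 in the controls. The second component held 11.2% and set control 1, at 18.93, apart from control 2 at -9.89 and control 3 at -6.34. The SD over genes of the difference between libraries was 0.247 for controls 2 and 3, but 0.399 for controls 1 and 2 and 0.364 for controls 1 and 3. The 3 pairs of surfactin libraries differed by SDs from 0.166 to 0.190. In control 1, 117 genes lay at least 2-fold from the mean of controls 2 and 3, of which 87 were higher. Controls 2 and 3 themselves lay at least 2-fold apart in 59 genes. Without control 1, the first component held 89.99% of the variance. Although controls 2 and 3 themselves differed by 2.32 for OP4 and 3.14 for HSP30, control 1 was high for both. It lay 2.74 above the mean of the other controls for OP4, an opaque-phase gene. For HSP30, of the heat shock and chaperone list, it lay 1.99 above that mean. It was low for PLB1, which encodes phospholipase B, at -1.23, and for FET99, a multicopper oxidase gene of iron uptake, at -1.39, all 4 chosen after their values were seen.

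**Figure D1:**
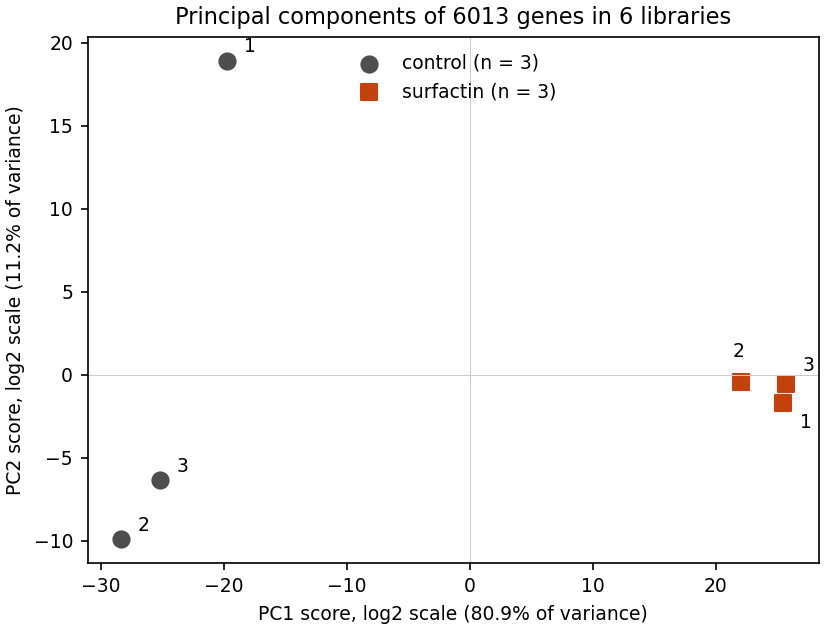
Scores of the 6 libraries on the first and second principal components of 6013 genes, on the log2 scale, with control libraries as circles, surfactin libraries as squares and replicate numbers beside them. The groups lie apart along the first component (80.9% of variance), and control 1 lies apart from the other controls along the second (11.2%).

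The second comparison asked which genes changed after 1 h of surfactin. The largest rise among genes with a symbol was in EBP1 (C6_01180C_A, chromosome 6), which encodes an NADPH oxidoreductase of the old yellow enzyme family. It went from -2.13 ± 0.07 (SD, n = 3) in controls to 2.19 ± 0.13 (SD, n = 3) in treated cultures, a rise of 4.32 ± 0.08 (limma adjusted p = 1.5e-06). Its relatives OYE32 and OYE23 rose by 3.04 ± 0.10 and 2.28 ± 0.12, and the glutathione transferase genes GTT13 and GST1 by 3.14 ± 0.17 and 2.38 ± 0.19. The largest fall was in YHB1 (CR_07790C_A, chromosome R), which encodes the flavohemoglobin that detoxifies nitric oxide, from 2.32 ± 0.36 (SD, n = 3) to -2.12 ± 0.17 (SD, n = 3), a change of -4.43 ± 0.18 (limma adjusted p = 1.8e-05). The copper-exporting ATPase gene CRP1 (C1_09250W_A) fell by 3.04 ± 0.12 and the heme biosynthesis gene HEM13 fell by 2.76 ± 0.17.

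The other large rises covered EFH1, a regulator of the APSES family, at 2.45 ± 0.16, the white-phase gene WH11 at 2.38 ± 0.22, and the ferric reductase gene FRE30 at 2.35 ± 0.29. LYS22, for homocitrate synthase of lysine synthesis, rose by 2.34 ± 0.08, and ICL1, for isocitrate lyase of the glyoxylate cycle, by 2.24 ± 0.38. PGA50, a putative GPI-anchored protein gene, rose by 3.21 ± 1.12 (limma adjusted p = 0.042) and the lactate transporter gene JEN1 by 2.60 ± 0.66 (limma adjusted p = 0.013). The other large falls were in UCF1 (-3.56 ± 0.17), CBF1 (-2.75 ± 0.12), CRD2 (-2.51 ± 0.17), IFE2 (-2.50 ± 0.18), the glucose transporter gene HGT6 (-2.48 ± 0.08), the transporter genes TPO3 (-2.36 ± 0.13) and CDR4 (-2.34 ± 0.15), PLB1 (-2.31 ± 0.33) and SOD5 (-2.02 ± 0.26), which encodes a superoxide dismutase of the cell surface. CBF1 encodes a transcription factor. The rule for naming these 24 genes required all 3 surfactin values to lie on one side of all 3 control values. Without surfactin 1, 2 or 3 the change of PGA50 was 3.34, 3.18 or 3.11, with limma adjusted p of 0.412, 0.632 or 0.588. Its limma adjusted p was 0.150 with the replicate number as a block. Limma without the mean trend gave an adjusted p of 0.0023 over all libraries, and the authors' deposited adjusted p was 0.0088. The p-values of PGA50 with the trend thus do not reflect the spread of its own values alone. Without surfactin 3 the change of JEN1 was 2.33 (limma adjusted p = 0.141).

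**Figure D2:**
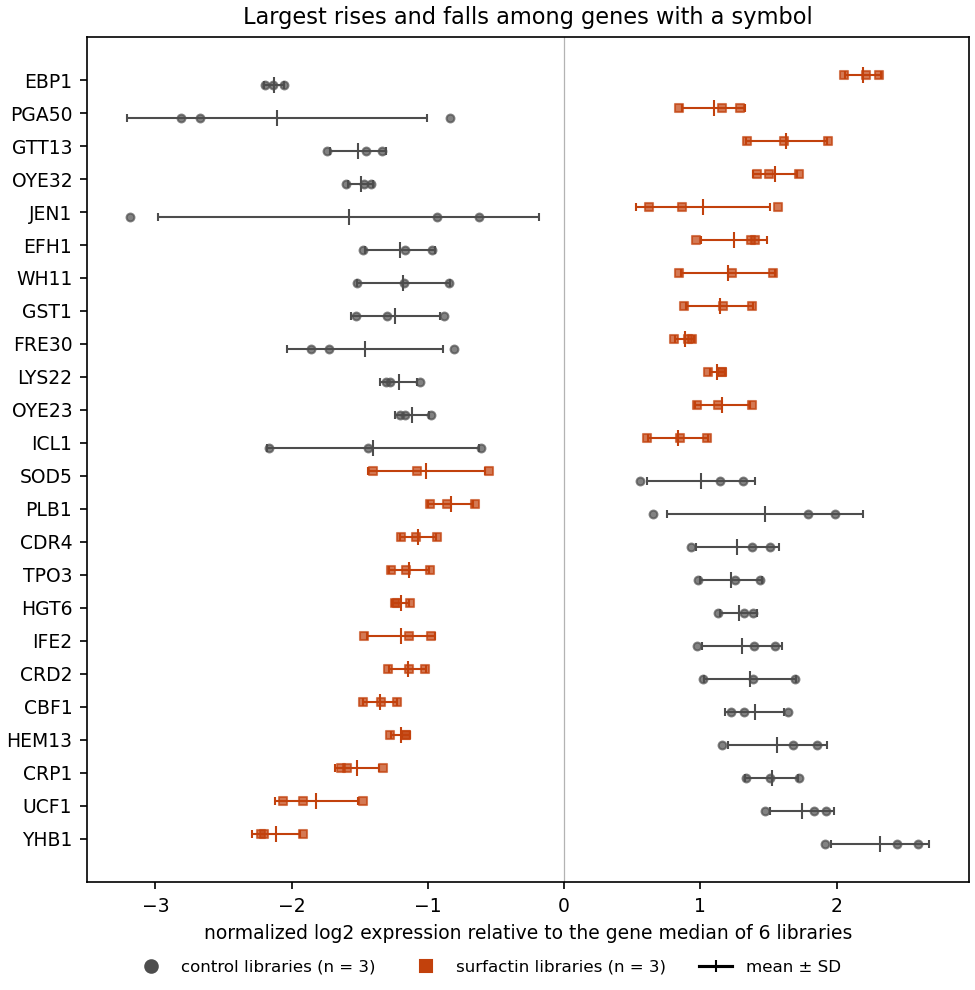
Normalized log2 expression, relative to each gene's median over 6 libraries, of the 12 largest rises and 12 largest falls among genes with a symbol, with each library as a point and mean ± SD per group (n = 3). The change is 4.32 in EBP1 and -4.43 in YHB1, and the 3 control values of PGA50 and JEN1 spread more widely than those of the other genes.

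In all, 3526 of 6013 genes (58.6%) passed, of which 1779 rose and 1747 fell, and 2487 did not pass. The change was at least 2-fold for 536 genes, 296 up and 240 down, a split that was 259 up and 302 down with quantile-normalized values. The median change over all genes was 0.0026. The 3 values of one group all lay above those of the other in 4035 genes (67.1%), where chance gives 10% of genes. The authors' deposited table holds 3488 genes with adjusted p under 0.05, of which 1739 were up and 1749 down, and with a change of at least 1.5-fold it holds 773 up and 617 down. Of the genes that passed here, 3322 also passed in the authors' deposited table.

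Groups of genes were compared over 38 lists with camera at a preset inter-gene correlation of 0.01, and 11 lists passed, 4 up and 7 down. With an estimated correlation none of the 38 passed, where the smallest adjusted p was 0.514. By fry, which asks only whether the genes of a list move on balance one way, 28 lists passed at adjusted p under 0.05. The counts adjusted over the list alone equalled those over all genes in 26 lists, and where they differed both are given.

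Genes for the parts of the ribosome fell while genes that assemble it rose. Of 72 measured cytosolic ribosomal protein genes, 69 fell and 2 rose, with a median of -1.03 (camera adjusted p = 4.1e-25; adjusted p = 0.514 with an estimated correlation). RPL8B fell by 1.32 ± 0.07, RPP2A by 1.27 ± 0.06, RPS20 by 1.24 ± 0.07 and RPS19A by 1.24 ± 0.08, while RPS27A rose by 0.88 ± 0.06 and RPL7 by 0.39 ± 0.08. Of 57 ribosome biogenesis genes, 49 rose and 2 fell (49 and 3 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 8.9e-12; adjusted p = 0.691 with an estimated correlation). MAK16, needed for the large subunit, rose by 1.28 ± 0.10, and NOP14 and UTP21, of the small-subunit processome, by 1.24 ± 0.09 and 1.09 ± 0.06. The exceptions NOP10 (-0.54 ± 0.06) and GAR1 (-0.26 ± 0.05) encode small proteins of the particle that pseudouridylates RNA. Genes for RNA polymerases I and III, which transcribe ribosomal and transfer RNA, moved with the biogenesis genes, with 9 of 12 rising and 0 falling (10 and 0 adjusted over the list alone), and a median of 0.39 (camera adjusted p = 0.0088; adjusted p = 0.514 with an estimated correlation). Among them RRN11 rose by 1.22 ± 0.06 and RPC53 by 0.86 ± 0.07. The biogenesis mean minus the ribosomal protein mean went from between -0.871 and -0.693 in the controls to between 0.733 and 0.752 in the surfactin libraries, a difference of 1.54 ± 0.06 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Control 1 differed from the other controls by medians of 0.071 for ribosomal protein and -0.074 for biogenesis genes.

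Genes of glycolysis and of respiration fell. Of 19 glycolysis and fermentation genes 16 fell and 1 rose, with a median of -0.73 (camera adjusted p = 1.4e-05; adjusted p = 0.691 with an estimated correlation). The hexokinase gene HXK2 fell by 1.59 ± 0.08, the phosphofructokinase genes PFK1 and PFK2 by 1.55 ± 0.12 and 1.55 ± 0.09, and GPM2 by 1.44 ± 0.14. HXK1, on the list by its symbol, rose by 0.20 ± 0.06 (limma adjusted p = 0.028), and whether it acts in glycolysis was not checked. Its limma adjusted p was 0.0626 to 0.103 without control 2, control 3 or any 1 of the surfactin libraries. The median of this list in control 1 was -0.254 relative to controls 2 and 3, toward the surfactin libraries. Of 32 nuclear genes for the respiratory chain and ATP synthase 28 fell and 0 rose (30 and 0 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 1.9e-08; adjusted p = 0.514 with an estimated correlation). The cytochrome c gene CYC1 fell by 1.16 ± 0.07, the cytochrome oxidase gene COX4 by 0.69 ± 0.06 and the ATP synthase genes ATP17 and ATP2 by 0.71 ± 0.08 and 0.66 ± 0.06. Of 23 tricarboxylic acid cycle genes 12 fell and 2 rose, with a median of -0.23 (camera adjusted p = 0.043; adjusted p = 0.763 with an estimated correlation). The aconitase gene ACO1 fell by 0.94 ± 0.11 and the succinate dehydrogenase gene SDH2 by 0.82 ± 0.06, while PYC2, for pyruvate carboxylase, which feeds the cycle, rose by 2.07 ± 0.09. The camera adjusted p of this list was 0.166 without control 1, with a median of -0.30, and 0.0657 without surfactin 3, with a median of -0.18.

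Other routes of carbon use were mixed. Of 5 genes of alternative, cyanide-resistant respiration 3 rose and 1 fell (camera adjusted p = 0.381), with rises of 2.14 ± 0.33 in AOX2 and 0.41 ± 0.08 in AOX1, the alternative oxidase genes, and a fall of 0.56 ± 0.12 in ALO1, for arabinonolactone oxidase. Of 18 genes of gluconeogenesis and use of other carbon sources 5 rose and 7 fell (camera adjusted p = 0.585). The regulator gene CAT8 rose by 1.22 ± 0.16, but PCK1, for phosphoenolpyruvate carboxykinase, fell by 1.68 ± 0.15 and the acetyl-CoA synthetase gene ACS1 by 1.02 ± 0.08. The median of this list was -0.13 and its mean 0.13, and camera gave a downward direction. Of 20 genes on the hexose transporter list, drawn by symbol, 6 rose and 4 fell (camera adjusted p = 0.664). HGT10, HGT18 and HGT1 rose by 1.69 ± 0.21, 1.49 ± 0.14 and 1.43 ± 0.11, and HGT7 fell by 1.44 ± 0.08. HGT10 is also on the osmotic stress, glycerol and trehalose list. The median, mean and camera direction of the hexose list were upward and its fry direction downward. Of 23 genes of fatty acid beta-oxidation and the glyoxylate cycle 9 rose and 5 fell (camera adjusted p = 0.397), with rises of 1.49 ± 0.29 in the carnitine acetyltransferase gene CTN1 and 1.13 ± 0.08 in the malate synthase gene MLS1. PXA1, for a peroxisomal fatty acid transporter, fell by 0.75 ± 0.10. Control 1 lay above the other controls by a median of 0.366 over the gluconeogenesis list, 0.213 over beta-oxidation and 0.189 over hexose transporters.

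**Figure D3:**
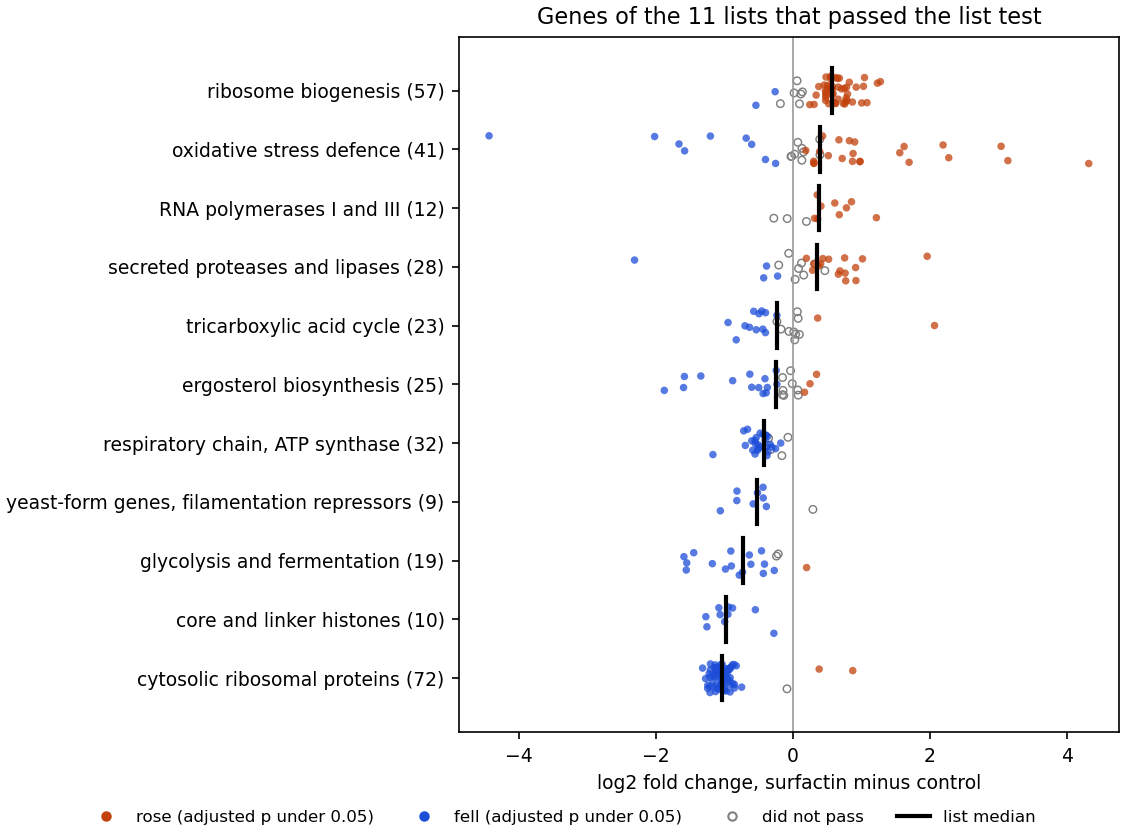
Log2 fold change, surfactin minus control, of each measured gene in the 11 lists that passed camera at the preset correlation, with the number of genes in parentheses, the list median as a bar, and genes that did not pass as open circles. Ribosomal protein genes gather around a median of -1.03 and ribosome biogenesis genes around 0.58, while oxidative stress genes reach from -4.43 to 4.32.

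Oxidative stress genes held the largest rise and the largest fall among genes with a symbol. Of 41 measured, 23 rose and 9 fell (24 and 9 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.0088; adjusted p = 0.691 with an estimated correlation). Besides EBP1, GTT13, OYE32 and OYE23, the catalase gene CAT1 rose by 0.44 ± 0.06, whereas YHB1 and SOD5 fell. Members with near-identical copies, such as AHP1 and AHP2 or TSA1 and TSA1B, are uncertain, since reads shared by copies may have been split. Of 20 genes of osmotic stress, glycerol and trehalose 3 rose and 8 fell (camera adjusted p = 0.381). TPS2 and TPS3, both of trehalose synthesis, fell by 1.83 ± 0.14 and 1.05 ± 0.11, and the trehalase gene NTH1 by 0.91 ± 0.11. HGT10, which is also on the hexose transporter list, rose by 1.69 ± 0.21. Of 22 heat shock and chaperone genes 8 rose and 6 fell (camera adjusted p = 0.731). HSP12 rose by 1.51 ± 0.11 and CPR6 by 0.90 ± 0.13, the ribosome-bound chaperone gene SSB1 fell by 0.67 ± 0.10 and the mitochondrial SSC1 by 0.63 ± 0.08, and HSP90 did not pass (-0.05 ± 0.07). This list lay 0.224 higher in control 1 than in the other controls at the median. Of 10 genes of the unfolded protein response and folding in the endoplasmic reticulum 2 rose and 5 fell (camera adjusted p = 0.330). ERO1 fell by 0.40 ± 0.07 and the sensor gene IRE1 by 0.34 ± 0.07. PDI1 and HAC1 rose by 0.26 ± 0.08 and 0.19 ± 0.06, but did not pass with the replicate block (limma adjusted p = 0.054 and 0.073). Of 27 proteasome genes 5 rose and 3 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.622). Their largest change was -0.28 ± 0.07 in RPN2, while PRE10 rose by 0.28 ± 0.07.

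Ergosterol genes fell as a group, while the other lipid lists did not pass camera. Of 25 ergosterol biosynthesis genes 14 fell and 3 rose, with a median of -0.24 (camera adjusted p = 0.019; adjusted p = 0.763 with an estimated correlation). UPC2, the transcriptional activator of the pathway, fell by 1.87 ± 0.15, ERG251 by 1.59 ± 0.16, the squalene epoxidase gene ERG1 by 1.58 ± 0.13, and ERG11, which encodes the azole target, by 0.88 ± 0.16. IDI1 rose by 0.35 ± 0.06. Over this list control 1 lay at a median of -0.168 relative to the other controls, toward the surfactin libraries. Of 9 genes of fatty acid synthesis and desaturation 6 fell and 2 rose (camera adjusted p = 0.382), with falls of 1.02 ± 0.17 in the fatty acid synthase gene FAS2 and 0.97 ± 0.09 in the desaturase gene OLE1 and rises of 0.59 ± 0.08 in FEN1 and 0.55 ± 0.08 in FAD3. Control 1 was also low over this list, at -0.234. Of 17 sphingolipid genes 7 fell and 4 rose (camera adjusted p = 0.382), with falls of 1.33 ± 0.07 in DES1 and 1.25 ± 0.13 in SUR2 and a rise of 0.57 ± 0.05 in the ceramide synthase gene LAC1, and control 1 at -0.163. Of 20 genes of phospholipid synthesis, translocation and cleavage 7 fell and 3 rose (camera adjusted p = 0.566). PLB1 fell by 2.31 ± 0.33 and OPI3, of phosphatidylcholine synthesis, by 0.76 ± 0.10, while the phospholipase gene PLC2 rose by 0.73 ± 0.10. Of 22 drug efflux genes 6 rose and 8 fell (camera adjusted p = 0.731), where the median was 0.04 but the mean -0.14 and the camera direction downward. MDR1, for a major facilitator pump, rose by 1.24 ± 0.08 and its activator gene MRR1 by 0.93 ± 0.11, while the ABC transporter genes CDR1 and CDR11 fell by 0.55 ± 0.10 and 1.80 ± 0.14 and QDR1 by 1.47 ± 0.11.

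Genes of the cell wall moved in both directions. Of 27 beta-glucan genes 11 rose and 8 fell (camera adjusted p = 0.566), with rises in SKN1 (1.62 ± 0.12), KRE1 (1.32 ± 0.18) and the exoglucanase gene XOG1 (1.17 ± 0.14) and falls in CRH12 (-1.11 ± 0.06) and SCW11 (-1.08 ± 0.13). PHR1 and PHR2, whose glucan-remodelling enzymes act at neutral and acidic pH respectively, moved apart, at 1.07 ± 0.08 and -0.84 ± 0.08. GSC1, for the beta-1,3-glucan synthase targeted by echinocandins, rose by 0.31 ± 0.09 (limma adjusted p = 0.018), and its adjusted p was 0.0602 without surfactin 2 and 0.0568 without surfactin 3. Of 16 chitin genes 8 rose and 3 fell (camera adjusted p = 0.381), where GFA1, at the first step of chitin precursor synthesis, rose by 0.79 ± 0.06 and the synthase gene CHS3 by 0.48 ± 0.08, while the chitinase genes CHT3 and CHT2 fell by 1.19 ± 0.13 and 1.10 ± 0.09. Of 37 mannosylation genes 8 rose and 14 fell (8 and 15 adjusted over the list alone; camera adjusted p = 0.381), with MNN22 at -1.16 ± 0.08 and the beta-mannosyltransferase gene BMT4 at 0.99 ± 0.08. The list's median change was -0.14, and control 1 lay at -0.130 relative to the other controls, toward the surfactin libraries. Of 34 wall protein and adhesin genes 7 rose and 14 fell (8 and 14 adjusted over the list alone, camera adjusted p = 0.330). PGA10, for a heme-binding protein of the surface, fell by 1.94 ± 0.18 and PGA26 by 1.46 ± 0.17. SAP10 rose by 1.96 ± 0.06, the largest change that passed in this list. Of 23 genes of wall integrity and calcium signalling 8 rose and 4 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.690). CRZ1, the calcineurin-responsive regulator, rose by 0.71 ± 0.14 and RCN1 by 0.56 ± 0.06. The 4 falls were of 0.56 ± 0.08 in SWI4, 0.47 ± 0.07 in VCX1, 0.24 ± 0.09 in PMC1 and 0.21 ± 0.07 in PKC1. PMC1 and PKC1 did not pass with the replicate block (limma adjusted p = 0.083 and 0.063).

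Genes of the yeast form and repressors of filamentation fell, 8 of 9 measured, with 0 rising (1 rose and 8 fell adjusted over the list alone) and a median of -0.51 (camera adjusted p = 0.022; adjusted p = 0.691 with an estimated correlation). NRG1 and TUP1, which repress filamentation, fell by 1.06 ± 0.10 and 0.58 ± 0.10. Of 18 hypha-associated genes 8 rose and 3 fell (camera adjusted p = 0.381). UME6, a regulator of filamentation, rose by 0.68 ± 0.08 and RBT4 by 0.93 ± 0.07, but ECE1, the candidalysin gene, fell by 1.29 ± 0.23 and IHD1 fell by 1.71 ± 0.16. The hyphal wall genes HWP1 and ALS3 did not pass, at -0.06 ± 0.26 and -0.13 ± 0.08. Of 10 white and opaque cell markers 5 rose and 2 fell (camera adjusted p = 0.524), with CZF1 at 0.69 ± 0.08 and EFG1 at -0.69 ± 0.16, and control 1 above the other controls by a median of 0.307. Of 28 secreted protease, lipase and phospholipase genes 16 rose and 4 fell (16 and 5 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.045; adjusted p = 0.514 with an estimated correlation). The protease gene SAP10 rose by 1.96 ± 0.06 and SAP30 by 0.92 ± 0.20, and the lipase genes LIP9 and LIP7 by 1.02 ± 0.24 and 0.92 ± 0.20. PLB1 fell by 2.31 ± 0.33, the largest change that passed in this list. The camera adjusted p of this list was 0.106 without control 1 (median 0.37), 0.0807 after removal of a trend with gene length (median 0.30), and 0.0569 with genes listed at 0 kept and 0.0601 on ranks, both with the median of 0.36.

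Metal genes rose and fell within each list. Of 25 iron and heme-iron uptake genes 11 rose and 7 fell (camera adjusted p = 0.381). The ferric reductase gene FRE9 rose by 1.74 ± 0.12, while the high-affinity permease gene FTR1 fell by 1.03 ± 0.06, CFL2 by 1.60 ± 0.17 and the heme oxygenase gene HMX1 by 1.39 ± 0.23. Of 19 genes of iron storage, iron-sulfur clusters, heme synthesis and their regulators 7 rose and 9 fell (7 and 10 adjusted over the list alone; camera adjusted p = 0.423), with HAP3 at 1.30 ± 0.10 and HEM14 at -1.27 ± 0.09. Of 13 zinc and copper genes 5 rose and 4 fell (camera adjusted p = 0.690). The copper transporter gene CTR1 rose by 1.56 ± 0.16, FRE7 by 2.23 ± 0.22 and the zinc regulator gene CSR1 by 1.04 ± 0.13. The zincophore gene PRA1 rose by 0.72 ± 0.20 (limma adjusted p = 0.017, and 0.0616 without surfactin 2), and the zinc transporter gene ZRT1 did not pass, at 0.49 ± 0.27, but without control 1 it changed by 0.81 (limma adjusted p = 0.0026). Control 1 lay above the other controls by medians of 0.160 over the zinc and copper list and 0.139 over the iron-use list.

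Genes of amino acid metabolism moved in both directions. Of 47 amino acid synthesis genes 17 rose and 7 fell (17 and 6 adjusted over the list alone; camera adjusted p = 0.119). Besides LYS22, the arginine synthesis genes ARG8, CPA1 and ARG3 rose by 1.56 ± 0.18, 1.25 ± 0.08 and 1.13 ± 0.07, while ILV5 and LEU1, of branched-chain synthesis, fell by 0.96 ± 0.07 and 0.84 ± 0.08. Of 21 sulfur, methionine and cysteine genes 10 rose and 8 fell (camera adjusted p = 0.449). The ATP sulfurylase gene MET3 rose by 2.18 ± 0.08, the sulfate transporter gene SUL2 by 1.67 ± 0.17 and MET15 by 1.57 ± 0.09, whereas MET6, for methionine synthase, fell by 1.03 ± 0.14 and MET13 by 1.26 ± 0.08, with control 1 at a median of -0.161 relative to the other controls. Of 37 genes of amino acid, oligopeptide and ammonium transport 12 rose and 14 fell (camera adjusted p = 0.422), with the peptide transporter gene PTR2 at 1.85 ± 0.39 and the permease genes CAN3 and HIP1 at -1.66 ± 0.07 and -1.63 ± 0.11. Its median was 0.04, its mean -0.07 and its camera direction downward.

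All 10 measured histone genes fell, with a median of -0.97 (camera adjusted p = 3.2e-05; adjusted p = 0.691 with an estimated correlation). HHT21 and HHT2, for histone H3, fell by 1.27 ± 0.07 and 1.25 ± 0.08 and HTA2, for H2A, by 1.08 ± 0.06, although the values of near-identical histone genes are uncertain one by one. Control 1 lay at a median of -0.216 relative to the other controls over these genes, toward the surfactin libraries. Of 34 genes of the cell cycle and DNA replication 12 rose and 6 fell (camera adjusted p = 0.524), with the cyclin gene PCL1 at 1.32 ± 0.13, the polo-like kinase gene CDC5 at 0.78 ± 0.06 and the ribonucleotide reductase gene RNR22 at -1.33 ± 0.21. Of 7 genes of autophagy and vacuolar proteases 0 rose and 3 fell (camera adjusted p = 0.381), namely ATG15 (-1.01 ± 0.11), PRB1 (-0.58 ± 0.07) and APE2 (-0.50 ± 0.07).

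The 27 lists that did not pass camera all passed fry's test for change in either direction, which does not compare a list with other genes. Their adjusted p with an estimated correlation was at least 0.691.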

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

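Removal of the gene length trend was the one alternative chosen after the result was seen. The genes that passed numbered 3526, and between 2845 (without surfactin 1) and 4275 (without control 1) with each library left out, 3500 to 3619 with other scalings, other limma options, genes at 0 kept or the length trend removed, 3488 by the authors' deposited p-values and 2550 at adjusted p under 0.01. Genes changed at least 2-fold numbered 536, and 491 to 618 with each library left out. At 1.5-fold they numbered 1433 (803 up, 630 down) and at 3-fold 157 (114 up, 43 down), where the threshold itself moves the count. Without the mean trend 548 genes changed at least 2-fold, 308 up and 240 down. No pairing of samples by replicate number was seen. Deviations of same-numbered libraries correlated at -0.041, 0.00609 and 0.0299, and 0 libraries correlated best with their own number. With 3 libraries per group this check could miss a shared pre-culture or batch. With the replicate block 3331 genes passed (3256 shared), 533 genes changed at least 2-fold, and 11 lists passed. Of 11 lists by camera, 9 to 11 passed with each library left out (9 without control 1), 10 with genes at 0 kept, 10 after length trend removal, 10 on ranks, 0 with an estimated correlation and 28 (12 up, 16 down) by directional fry, which does not compare a list with other genes. Short of the estimated correlation, the lists lost were those of the tricarboxylic acid cycle (without control 1 or surfactin 3) and of secreted hydrolases (without control 1, with genes at 0 kept, after length trend removal and on ranks). The first component held 78.7% to 89.99% of the variance with each library left out, the highest without control 1. Of 225 named genes that passed, 0 changed direction; 9 lost the call with the block, 1 to 19 with a library left out (1 without control 1, 19 without surfactin 1), 0 under centring or quantile normalization, and 1 to 9 under other limma options, with genes at 0 kept or with the length trend removed. HWP1 and HSP90, which did not pass, changed sign. HWP1 lay between -0.23 and 0.22 with a library left out (0.22 without control 3, 0.026 without surfactin 2 and 0.028 without surfactin 3) and HSP90 between -0.082 and 0.00074 (the latter without control 1); the cause was not tested. A stricter filter on low values could not be run, since centred values hold no levels, and pseudocounts, size factors and count tests had no place on log2 values without counts. Depth is unknown, so what it limits cannot be given.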

Other observations

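The tests of library scale, of copper and of the source of the genes higher and lower in control 1, the symbol families and the genes without a symbol were chosen only after the results were seen. Families of genes that share a symbol stem were tested with camera over 74 stems with at least 6 measured members, and 9 passed, 0 of them with an estimated correlation. Purine synthesis genes, the ADE stem, held 8 falls and 0 rises among 9 members, with a median of -0.71 (camera adjusted p = 0.0069; adjusted p = 0.802 with an estimated correlation). ADE6 fell by 1.30 ± 0.17, ADE13 by 0.96 ± 0.13 and ADE1 by 0.77 ± 0.07 (SE, n = 3 per group), and control 1 lay at a median of -0.401 relative to the other controls over this stem, toward the surfactin libraries. Secretory pathway genes, the SEC stem, held 17 falls and 2 rises among 27 members, with a median of -0.23 (camera adjusted p = 0.014; adjusted p = 0.802 with an estimated correlation). Secreted aspartic protease genes, the SAP stem, held 10 rises and 0 falls among 13 members, with a median of 0.41 (camera adjusted p = 0.041; adjusted p = 0.728 with an estimated correlation). The ERG stem, which overlaps the ergosterol list, did not pass. It held 10 falls and 2 rises among 20 members, with a median of -0.195 (camera adjusted p = 0.072, and 0.802 with an estimated correlation).

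The largest rise of all that passed was in a gene without a symbol, CR_04820W_A (CAALFM_CR04820WA), at 5.27 ± 0.19 (SE, n = 3 per group; limma adjusted p = 1.1e-05), higher in 3 of 3 surfactin libraries. The MRV genes, 7 members of which 6 are on chromosome 5, were higher in control 1 than in the other controls by a median of 1.36, and 2 of them rose with surfactin. Median changes over the genes of each of the 8 chromosomes lay between -0.064 on chromosome 6 and 0.044 on chromosome 5. Other splits of the 6 libraries into 3 and 3 gave at most 0 genes, against 3526 for the real split, at most 0 genes changed at least 2-fold against 536, and at most 10 lists against 11 (1 of 10 splits, the real one, with a result as large). At an unadjusted p under 0.05 limma gave 8 to 126 genes in the other splits, against 3827. The 10 splits are too few for a share under 0.05. Each other split puts treated and control libraries in both groups, so the treatment difference widens the spread within groups. Its low counts are therefore no baseline for the real split.

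Ribosomal protein genes fell while ribosome biogenesis genes rose. A single wrong factor for a library would move both lists alike, but the gap between their mean changes was 1.54 ± 0.06. It lay in the same direction in 3 of 3 surfactin libraries. The lists were compared because they had been seen to part, so a gap was given beforehand. A scale that varies with expression level could not be checked, since the values hold no levels. A trend with gene length (medians of 678.5 and 1428 bases) could part the lists. The gap of medians was 1.61 but stayed 1.63 after that trend was removed, and it was 1.57 without control 1. Other technical sources, such as the authors' counting, were not tested, so a response to surfactin stays a hypothesis found on these data. The exact two-sided permutation p of the gap was 0.1, the smallest that 3 against 3 can give, so it cannot decide.

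Control 1 stood apart from controls 2 and 3, and no biological explanation was tested, as the design gives none. Gene length accounted for 2.67% of the variance of this difference, which argues against a length trend as its cause. Cells or RNA from a treated culture may be present, and the 4 genes at least 8-fold higher in every surfactin library were higher in control 1 by a median of 0.53 (bootstrap interval -0.013 to 1.12), but EBP1, the one with a symbol, was at -0.013. Of the 87 genes at least 2-fold higher in control 1, 42.5% (37 genes; exact binomial 95% interval 32.0% to 53.6%) were at least as high in the surfactin libraries, and of the 30 genes at least 2-fold lower, 33.3% (10 genes; interval 17.3% to 52.8%) were at least as low there. A treated culture as the source of all these genes would put over 90% beyond control 1, and both intervals lie below that. The bound for rejection was first an upper limit under 50%, which the 87 genes missed and the 30 genes would also miss. It was moved to 90% after the share of the 87 genes was known. These genes were picked for extreme values in control 1, which can itself lower both shares. The intervals also treat genes of 1 library as independent, so they do not settle that source. A small admixture stays open with 4 genes.

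Although the zinc and copper list as a whole did not pass (camera adjusted p = 0.690), the reductase gene FRE7 rose by 2.23 ± 0.22, the copper transporter gene CTR1 by 1.56 ± 0.16 and the regulator gene MAC1 by 0.68 ± 0.06, whereas CRP1 fell by 3.04 ± 0.12 and the metallothionein gene CUP1 by 1.04 ± 0.14. Lower copper inside treated cells might give these changes, and it would also raise SOD3, the manganese superoxide dismutase gene, and lower SOD1, the copper-zinc form. SOD3 instead changed by -0.68 ± 0.09 and SOD1 rose by 0.52 ± 0.07 (limma adjusted p = 0.00058 and 0.00071), against that prediction. FRE7, CTR1, MAC1, CRP1 and CUP1 moved as lower copper might give. CUP1, MAC1, SOD1 and SOD3 were chosen after their values were seen, so they cannot decide on that explanation. CTR2, CUP2 and ATX1 of the same list did not pass.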
